A study of Homo sapiens with 6 samples.

How the data were processed

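RNA was sequenced from 6 samples labelled as a gemcitabine-resistant derivative of PANC-1, a human pancreatic ductal carcinoma line. The labels put 3 libraries in a control group and 3 in a group with SRSF3 knockdown, and name no batch, culture date or origin of the replicates. The p-values therefore measure only the spread between these libraries, which can be technical. Per the labels' protocols, one preparation selected polyadenylated RNA, and a stranded preparation with rRNA depletion was used for the long noncoding RNAs. Which preparation gave the deposited values is not given in the sources used here.

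The authors deposited FPKM values (fragments per kilobase of gene, scaled to the library's total) per gene symbol in an mRNA table of 19912 rows and a lncRNA table of 14145 rows. HISAT2, StringTie, Cuffdiff and edgeR are named per the submitters' processing notes, with no role or version. The genome build, annotation and use of strand in counting are not given in the sources used here, so no coordinates are printed. Without known strand, reads of an antisense lncRNA and its partner gene cannot be told apart, and reads of genes with near-identical copies, such as ribosomal protein genes, can have been split. The tables hold 31 repeated symbols and 27 symbols turned into dates, which were kept as rows; none of these is named.

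The deposited FPKM values were checked for the steps that whole fragments leave. A single total per library and a single length per gene gave whole fragment numbers, within 0.003 fragments, for 19406 of the 19434 rows above 0 in at least 3 libraries (99.9%). The recovered totals were 24558238, 25560682 and 27351642 fragments in control libraries 1 to 3 and 25619023, 24903382 and 27300517 in knockdown libraries 1 to 3. The same totals held for both tables, with 14776 of 14803 mRNA rows and 4630 of 4631 lncRNA rows on the grid. This argues against the tables coming from separate preparations. At these depths 1 FPKM corresponds to between 24.6 and 27.4 fragments per kilobase. The remaining 28 rows are called rows off the step grid. On simulated data, 300 of 300 rows built from whole fragments were placed on the grid and 0 of 300 rows with 1 group shifted were. Of 1000 rows above 0 in all 6 libraries, shuffled between genes of like level, 1 was placed, over a shorter range of lengths than was searched for the real rows. Rows above 0 in fewer libraries were not shuffled and can fit by chance more often.

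Each table was tested on its own with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The mRNA table was tested on log2(FPKM + 1) for rows with a mean of at least 0.5 FPKM, and the lncRNA table on log2(FPKM + 0.1) for rows with a mean of at least 0.1 FPKM. Fold changes are on these scales and understate the change of low genes. No rescaling between libraries was applied. Simulated data were built from the mean levels of the real rows and the library totals, with an assumed spread between replicates, equal in all libraries. On these data the mRNA fit called 20.4% of genes changed 1.2-fold, 94% at 1.5-fold and 100% at 2-fold, with 16 of 10584 unchanged genes called. The lncRNA fit called 6.1% at 1.5-fold, 16.7% at 2-fold and 55.3% at 4-fold, with 1 of 2918 unchanged genes called. The real spread differed between libraries, so these rates need not hold for the real data.

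Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the 30 lists, the 25 with at least 5 tested members were tested with camera (inter-gene correlation 0.01), again with an estimated correlation, and with fry. Camera compares a list with the other genes of its table. The fry p tests whether a list's genes move, on balance, one way, and compares them with no other genes. Symbols were matched also through older names in a table of RefSeq genes. The rule named SRSF3, the 8 largest rises and 8 largest falls past the threshold with a group mean of at least 2 FPKM and no overlap between groups, and up to 4 members of each list with the smallest p. In the lncRNA table it named up to 5 per direction with a group mean of at least 0.5 FPKM, by unadjusted p because fewer than 5 passed. Not every gene that the rule picks is given. Single values were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

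The alternatives were another pseudocount, no filter and a stricter filter, median scaling, quantile normalization, robust empirical Bayes, a 2-fold minimum, each library left out and a replicate block. Transcripts summed per gene and the authors' own calls did not apply, because the tables hold genes and no p-values. Several choices were made after seeing the data. These were the step grid and its tolerance, the fit without the rows off the grid, limma voom on recovered fragment numbers, the addition of the largest changes among rows on the grid and of FANCI, RPA3, GEN1, SLX4 and DCK, the naming of KRT8, CDH1, VIM, HNRNPL, HNRNPR, PDX1 and HNF4A for their levels, the longest gene length searched (250000 bp), every test of an explanation with its bound, and the patterns chosen for weighing. The test for whole-number shifts was first counted per value, which chance met often, and then per row, and the choice among fitting lengths was revised once, which added 1 row. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the grid.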

Results

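Expression was measured in 6 libraries of cells labelled as gemcitabine-resistant PANC-1, 3 labelled control and 3 labelled SRSF3 knockdown. SRSF3 is a serine/arginine-rich splicing factor, and the series title ties it to splicing of the lncRNA ANRIL (CDKN2B-AS1), to m6A and to resistance to gemcitabine, a nucleoside drug. The comparison of the groups asks what differs in cells carrying the knockdown label. Library totals recovered from the values ran from 24558238 to 27351642 fragments. Values are deposited FPKM, given as mean ± SD with n = 3 per group.

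For SRSF3 itself no fall was detected in the libraries labelled knockdown. The interval of the fit without rescaling excludes a fall of more than 9.67%, while the lowest log2 change over the scalings was -0.12. Its level was 38.6 ± 1.40 FPKM in controls and 37.5 ± 0.900 FPKM in the libraries labelled knockdown (SD, n = 3), from 6468 to 7640 fragments per library. The change was -2.65% (95% interval from -9.67% to 4.92%), with a log2 change of -0.04 (SE 0.05, limma adjusted p = 0.612). An exact permutation test gave p = 0.3, where 0.1 is the smallest possible. The value sums all isoforms and does not measure protein. Every direction below is that of libraries carrying the knockdown label, in which no fall of SRSF3 was detected.

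**Figure D1:**
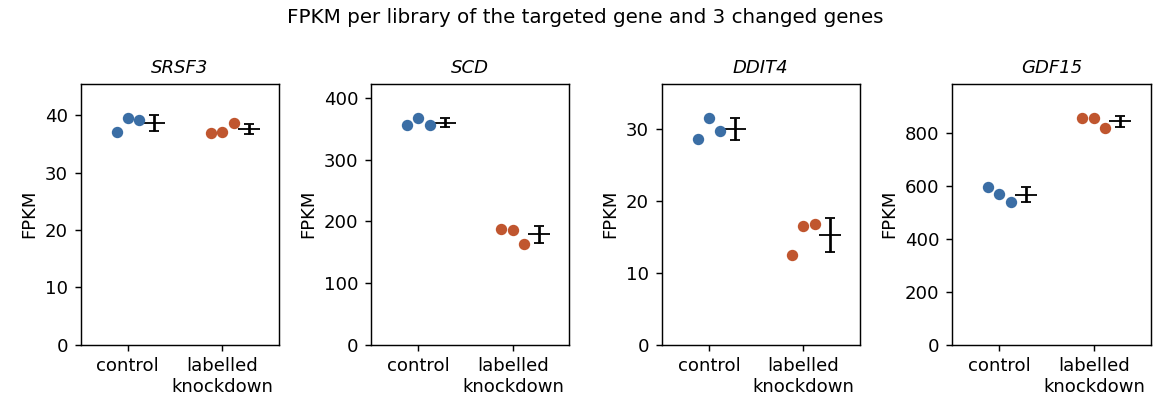
FPKM of SRSF3, SCD, DDIT4 and GDF15 in each library, by group, with points for libraries and bars for mean ± SD (n = 3). SRSF3 overlaps between groups, at 38.6 and 37.5 FPKM, while SCD falls from 360.3 to 178.7 FPKM.

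ANRIL was listed at 0.172 ± 0.029 FPKM in controls and at 0, 0 and 0.00913 FPKM in the libraries labelled knockdown. This row is off the step grid, so it does not follow the formula that fits the other lncRNA rows above 0 in at least 3 libraries, and it is not read here as a change in expression. Its mean is below the filter of 0.1 FPKM, so limma did not test it, and an exact permutation test gave p = 0.1, the smallest possible. Its neighbours at the same locus were on the grid. The kinase inhibitor gene CDKN2A had 0 to 2 fragments per library, CDKN2B stood at 0.639 ± 0.071 and 0.713 ± 0.101 FPKM (limma adjusted p = 0.573), and MTAP, of methionine salvage, at 2.99 ± 0.182 and 3.34 ± 0.086 FPKM (limma adjusted p = 0.183).

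In all, 28 rows were off the step grid, ANRIL and 27 in the mRNA table. They include BRCA1, BRCA2, DEK, FANCB, HELB, MRNIP, NFRKB, OTUB1, PARG, PML, POT1, PPP4C, RAD51AP1, RBBP8, RECQL5, RTEL1, SIRT6, SIRT7, SLF2, TERF2IP, TFPT, TRIP12, UIMC1, ZCWPW1 and ZNF365. Of the rows, 5 belong to the list of homologous recombination genes, against 0.062 expected among 14803 rows (Fisher's exact p = 3.66e-09). Of the 28, 20 were lower and 8 higher in the libraries labelled knockdown, and 27 had groups that did not overlap. Among 10799 tested mRNA genes on the grid that share was 37.7%, where chance gives 10%. By the rule for named genes, the largest changes of the table included RECQL5, PML, SIRT6, PPP4C and TERF2IP among rises and MRNIP, RAD51AP1, SIRT7, RBBP8 and ZCWPW1 among falls. All of these are off the grid and are not read here as changes in expression.

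Among mRNA rows on the grid, PRR15L fell from 5.59 ± 0.945 to 1.78 ± 0.103 FPKM (log2 -1.24, SE 0.10, limma adjusted p = 5.51e-05). The secreted trefoil peptide gene TFF1 fell from 7.85 ± 0.752 to 3.06 ± 0.465 FPKM, and the fatty acid desaturase gene SCD from 360.3 ± 6.88 to 178.7 ± 13.6 FPKM. TNNI2, the stress gene DDIT4 and the myosin chaperone gene UNC45A also fell, by 0.97, 0.94 and 0.79 on the log2 scale. TMEM14C fell by 0.82 (log2), a call lost without knockdown library 2 (adjusted p = 0.0696), with no filter (0.122) and with robust empirical Bayes (0.149), and by 0.50 without control library 3. FAM213B rose from 0.671 ± 0.1001 to 3.10 ± 1.62 FPKM (log2 1.23), the muscle and YAP-responsive gene ANKRD1 from 1.62 ± 0.267 to 4.38 ± 0.392 FPKM (log2 1.04), and S100P, CYP26B1, RGS2, FOSL1, TNS4 and TAGLN by 0.68 to 0.79 (log2).

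Over the mRNA table, 1819 of 10823 genes passed the limma threshold (Benjamini-Hochberg), 1179 higher and 640 lower in the libraries labelled knockdown. Without the rows off the grid the count was 1780, with 1159 higher and 621 lower. Changes were mostly small. Only 16 calls reached 2-fold, 10 of them off the grid, which left 6 on it; with a pseudocount of 0.1, 29 did, 13 of them off the grid, and voom on rows on the grid gave 26. Quantile normalization gave 817 higher and 808 lower genes, a share of 50.3% higher against 64.8% as reported. Groups did not overlap in 4075 of 10799 genes on the grid (37.7%, where chance gives 10%). The FPKM of all mRNA rows summed to between 275359 and 285701 in controls and to 336887, 308101 and 287148 in knockdown libraries 1 to 3. The count of changed genes was 1079, 643 and 646 without control libraries 1, 2 and 3, 842 without knockdown library 2 and 2742 without knockdown library 3.

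Mitotic genes were lower. Of 35 tested members of the list, 20 fell and 0 rose (22 fell when adjusted over the list alone), with a camera adjusted p = 1.23e-13 and adjusted p = 0.0659 with an estimated correlation. TOP2A, which untangles DNA, fell from 43.2 ± 3.52 to 28.8 ± 2.95 FPKM, the kinetochore gene CENPF from 10.2 ± 0.626 to 6.81 ± 0.707 FPKM, and separase (ESPL1) and the spindle motor KIF11 by 0.43 and 0.44 (log2). DNA replication genes went both ways, with 5 lower and 2 higher of 39 (the same numbers adjusted over the list alone). CLSPN fell by 0.27 and CCNE1 rose by 0.38 (log2), and the list did not pass (camera adjusted p = 0.408), though it did with quantile normalization (adjusted p = 0.0274, against 0.299 with median scaling). The mitosis list also passed in 8 of the other splits of the 6 libraries, with a smallest adjusted p = 4.62e-09. Each other split sets 2 libraries of one label and 1 of the other against the reverse, so part of any real difference stays in it. Passes there that are weaker than in the real split do not by themselves count against a list.

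Genes of cholesterol synthesis were lower, with 15 of 25 past the threshold and 0 higher (19 lower and 1 higher adjusted over the list alone). The camera adjusted p = 8.29e-11, and the adjusted p = 0.0659 with an estimated correlation. INSIG1, which holds back activation of sterol synthesis, fell from 45.6 ± 0.419 to 31.8 ± 0.244 FPKM, and the synthesis enzymes HMGCS1 and SQLE by 0.42 and 0.30 (log2). In the list of the unfolded protein and ATF4 responses, 12 of 29 fell and 0 rose (13 lower and 1 higher adjusted over the list alone), with a camera adjusted p = 5.64e-05 and adjusted p = 0.161 with an estimated correlation. DDIT4 fell from 29.96 ± 1.48 to 15.3 ± 2.38 FPKM, the ER-stress gene HERPUD1 from 42.8 ± 0.813 to 32.9 ± 1.01 FPKM and the serine synthesis enzyme PHGDH by 0.44 (log2). The cholesterol list also passed in 7 of the other splits of the libraries (smallest adjusted p = 1.85e-05) and the unfolded protein list in 1 (0.0251).

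In the homologous recombination list, 29 tested members were on the grid. Of these, 7 fell and 1 rose, with 11 lower and 1 higher adjusted over the list alone. The camera adjusted p = 1.27e-03 and the adjusted p = 0.107 with an estimated correlation. FANCI, of the Fanconi anaemia pathway, fell from 19.2 ± 0.664 to 15.5 ± 0.229 FPKM and RPA3, of the single-strand binding complex, from 8.66 ± 0.166 to 6.84 ± 0.419 FPKM. GEN1 fell by 0.34 (log2), a call lost without control library 3 (adjusted p = 0.0749) or knockdown library 2 (0.0633). SLX4 rose by 0.27 (log2), a call lost without control library 2 (0.0722), control library 3 (0.0883) or knockdown library 2 (0.0739). BRCA1, BRCA2, RAD51AP1 and RBBP8, off the grid, have log2 values of -0.85, -0.52, -1.44 and -1.20, and with them the counts are 11 lower and 1 higher of 33 (15 and 1 adjusted over the list alone), with a camera adjusted p = 1.34e-06 and adjusted p = 0.0659 with an estimated correlation. With them the list also passed in 5 of the other splits of the libraries (smallest adjusted p = 0.00217). Of 15 tested genes of non-homologous end joining, XRCC6 alone rose, by 0.22 (log2), and 0 fell (0 adjusted over the list alone, camera adjusted p = 0.673). Its call was lost with median scaling (adjusted p = 0.0576) and without control libraries 1, 2 and 3 (0.121, 0.145 and 0.155) or knockdown libraries 1 and 2 (0.0618 and 0.124).

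**Figure D2:**
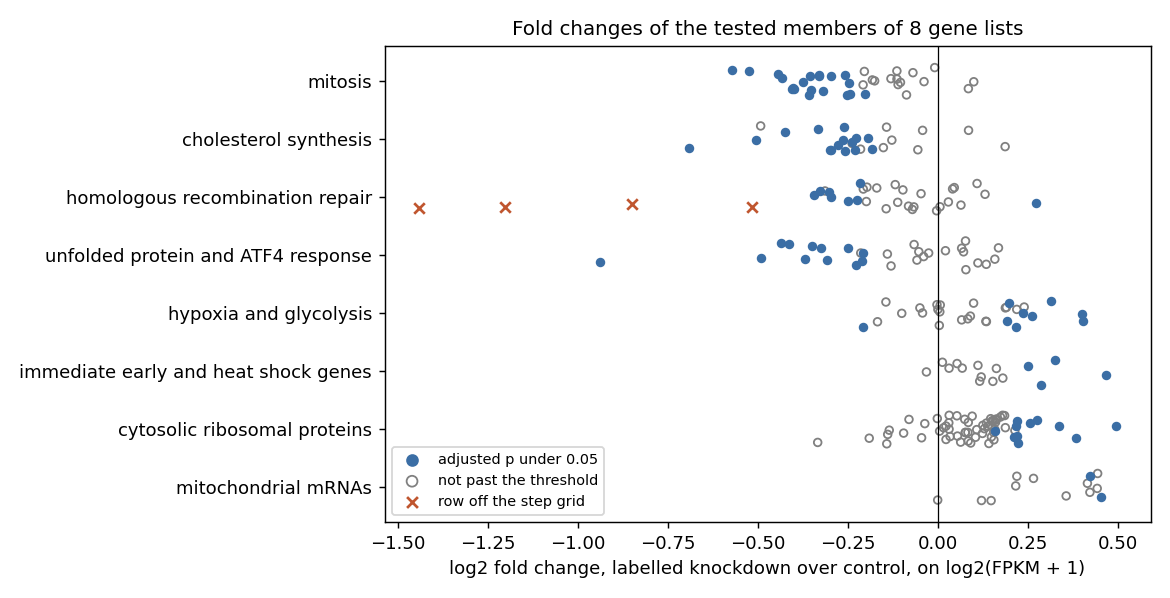
Log2 fold change (labelled knockdown over control, on log2(FPKM + 1)) of each tested member of 8 gene lists, filled where the limma adjusted p is under 0.05 and crossed where the row is off the step grid. Mitosis has 20 lower and 0 higher members, and RAD51AP1, RBBP8, BRCA1 and BRCA2, the crosses at log2 -1.44 to -0.52, are off the grid.

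Genes of hypoxia and glycolysis included 8 higher and 1 lower of 29 (9 and 1 adjusted over the list alone). SLC2A1, the main glucose transporter, rose from 333.2 ± 15.3 to 440.7 ± 20.8 FPKM and SLC2A3 from 14.1 ± 0.141 to 18.99 ± 0.412 FPKM. The list's camera adjusted p = 0.0355, with adjusted p = 0.684 with an estimated correlation and 0.129 after quantile normalization (4 higher and 0 lower), and it was also lost without control library 1 (0.0669), control library 3 (0.0534) or knockdown library 1 (0.0713). It also passed in 1 of the other splits of the libraries (0.0457). Immediate early and heat shock genes rose in 4 of 15 (6 adjusted over the list alone), among them JUN, from 20.97 ± 0.065 to 29.4 ± 0.825 FPKM, and EGR1, from 36.6 ± 0.420 to 46.1 ± 1.18 FPKM. That list had a camera adjusted p = 0.0036, with adjusted p = 0.268 with an estimated correlation and 0.0634 after quantile normalization (4 higher and 1 lower), and it passed in 0 of the other splits (smallest adjusted p = 0.0633).

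Ribosomal protein genes had 11 of 64 higher and 0 lower (12 adjusted over the list alone), with a camera adjusted p = 0.00334, adjusted p = 0.684 with an estimated correlation, 0.615 after quantile normalization, 0.140 at a mean of at least 5 FPKM, 0.242 with fry and 0.178 without knockdown library 1. RPL17 rose from 6.62 ± 0.680 to 9.71 ± 0.370 FPKM (log2 0.49), more than the list's median log2 change of 0.12. The far more abundant RPL18 and RPS19, at 149.5 and 176.3 FPKM in controls, each rose by 0.22 (log2). With quantile normalization 6 rose and 3 fell, with a median log2 change of -0.0005. Mitochondrial mRNAs had 2 of 13 higher (6 adjusted over the list alone, 0 higher with median scaling), with a camera adjusted p = 0.0284 and adjusted p = 0.684 with an estimated correlation. All 13 were highest in knockdown library 1, where MT-ND2 reached 6028 FPKM against 3388 to 3702 FPKM in controls and 4595 and 4179 FPKM in the other knockdown libraries, and its own call was lost with median scaling (0.0544) and without control libraries 1, 2 and 3 (0.115, 0.149 and 0.188) or knockdown library 2 (0.104), while without knockdown library 1 its log2 change was 0.30 against 0.45. The mitochondrial list gave an adjusted p = 0.641 after quantile normalization (1 higher and 1 lower), 0.135 at a mean of at least 5 FPKM, 0.258 with fry, 0.178 without knockdown library 1, 0.0669 without control library 1 and 0.0724 without control library 3. Quantile normalization gives rows of the same rank the same value in every library. It can by itself remove a change of very abundant rows such as MT-ND2, so the mitochondrial loss there does not decide whether these genes changed. The ribosomal and mitochondrial lists both also passed in 6 of the other splits of the libraries. The smallest camera adjusted p there was 4.94e-09 for ribosomal and 5.32e-05 for mitochondrial genes, each smaller than in the real split. These lists and that of immediate early and heat shock genes were fixed as signs of RNA quality or sample handling. Pairs of control libraries differed by a chi-square per gene of 3.27 to 6.64 against counting noise, pairs with knockdown library 1 by 15.3 and 31.2, and the remaining knockdown pair by 10.7. A difference in handling between the groups was not tested and stays open for every change given here.

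Lists tied to the study's question did not pass as groups in camera. Of 21 genes of gemcitabine transport and metabolism, 4 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.673). NT5E, an ecto-nucleotidase, rose from 59.3 ± 0.622 to 76.1 ± 4.30 FPKM, while NME1, DCTPP1 and CTPS1, of nucleotide metabolism, rose by 0.23 to 0.25 (log2). Without control library 2 the adjusted p of these 3 was 0.0869, 0.113 and 0.101, and without control library 3 it was 0.0654, 0.116 and 0.141. DCTPP1 also lost its call with quantile normalization (0.146) and without knockdown library 2 (0.1001), and CTPS1 with quantile normalization (0.0832) and without control library 1 (0.0758), knockdown library 1 (0.0761) or knockdown library 2 (0.109). The list's median was -0.0012 and its mean 0.0459 (log2), and with quantile normalization 2 rose and 3 fell. The activating kinase gene DCK stood at 10.4 ± 0.176 and 9.60 ± 1.05 FPKM (limma adjusted p = 0.293). Of 10 efflux pump genes, 0 passed in limma, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 0.673); ABCC3 had the smallest limma adjusted p = 0.0934, and the list's median was 0.01 against a mean of -0.01 (log2). Of 13 SR splicing factors, SRSF2 rose by 0.21 and SRSF5 fell by 0.17 (log2; 1 and 1 adjusted over the list alone, camera adjusted p = 0.628), and without control libraries 1, 2 and 3 both calls were lost (adjusted p = 0.0804, 0.0894 and 0.126 for SRSF2, also lost with quantile normalization, 0.203, and 0.102, 0.153 and 0.119 for SRSF5, also lost without knockdown library 2, 0.134).

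Among 23 hnRNP genes, PTBP1 rose by 0.28 and HNRNPH1 and PTBP3 fell by 0.38 and 0.22 (log2; 1 and 0 adjusted over the list alone, camera adjusted p = 0.628, and 0.534 and, lower, 0.0328 after median scaling and quantile normalization). The list's median was 0.02 and its mean -0.02 (log2). The PTBP1 call was lost without control library 2 (adjusted p = 0.0635), control library 3 (0.0625) or knockdown library 2 (0.0507). The HNRNPH1 call was lost with quantile normalization (0.0651) and without control libraries 1 and 3 (0.113 and 0.146) or knockdown libraries 2 and 3 (0.125 and 0.0688). The PTBP3 call was lost without control libraries 1, 2 and 3 (0.0575, 0.145 and 0.171) or knockdown libraries 1 and 2 (0.0884 and 0.154). Of 18 m6A genes, RBM15B, of the writer complex, rose by 0.18 (log2; 0 adjusted over the list alone, camera adjusted p = 0.673). Its call was lost with quantile normalization (0.131) and without control libraries 1, 2 and 3 (0.0939, 0.111 and 0.129) or knockdown libraries 1 and 2 (0.0654 and 0.0665). Of 27 Polycomb genes, PCGF1 and PHC2 rose by 0.38 and 0.34 (log2; 2 adjusted over the list alone, camera adjusted p = 0.354), while the list's median was -0.03, and with either scaling 2 rose and 2 fell.

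In the lncRNA table, 0 of 3092 rows passed the limma threshold, with 284 at an unadjusted p under 0.05. On simulated data with an assumed spread between replicates, the fit called 16.7% of lncRNAs changed 2-fold. At that spread, changes of that size were mostly not detectable. With a mean of at least 1 FPKM 12 rows passed, with a replicate block 1, and with limma voom on recovered fragments 57 (43 higher). That voom fit had 375 prior degrees of freedom against 3.90 in the fit reported, so it almost ignores each row's own spread. By unadjusted p, the highest-ranked rows included UCA1, at 5.93 ± 0.242 and 10.2 ± 1.28 FPKM, GLIS3-AS1, at 0.560 ± 0.078 and 1.63 ± 0.220 FPKM, AC069200.1, listed at 0 in all controls and at 0.632 ± 0.150 FPKM, AL161431.1, at 67.4 ± 4.18 and 97.7 ± 7.17 FPKM, and AC093673.1. Those lower in the libraries labelled knockdown were AP003390.1, at 1.26 ± 0.063 and 0.371 ± 0.085 FPKM, AL391839.2, AL157871.5, AL049780.2 and AL391095.3. The smallest limma adjusted p among the named rows was 0.0681. UCA1, GLIS3-AS1, AL161431.1 and AC093673.1 are among the 12 that passed with a mean of at least 1 FPKM (adjusted p = 0.0435), AL161431.1 is the row that passed with the replicate block (0.0250), and these 4 and AL157871.5 are among the 57 of the voom fit.

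Of 14 snoRNA host genes, 0 passed singly in limma, with SNHG10 at an unadjusted p of 0.0237 (0 adjusted over the list alone), and the list was higher with a camera adjusted p = 0.0377 and adjusted p = 0.245 with an estimated correlation. It was lost after quantile normalization (adjusted p = 0.528) and without control library 1 (0.135), control library 3 (0.0941), knockdown library 2 (0.141) or knockdown library 3 (0.0953), and passed in 0 of the other splits (smallest adjusted p = 0.0588). Of 28 lncRNAs often studied in cancer, 0 passed in limma, with 8 at an unadjusted p under 0.05 (1 higher, UCA1, adjusted over the list alone, camera adjusted p = 0.685). MALAT1 stood at 4.10 ± 0.300 and 2.83 ± 0.546 FPKM and NEAT1 at 2.53 ± 0.068 and 1.88 ± 0.021 FPKM, with limma adjusted p = 0.357 and 0.399, and adjusted p = 5.85e-10 and 1.05e-10 in the voom fit.

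**Figure D3:**
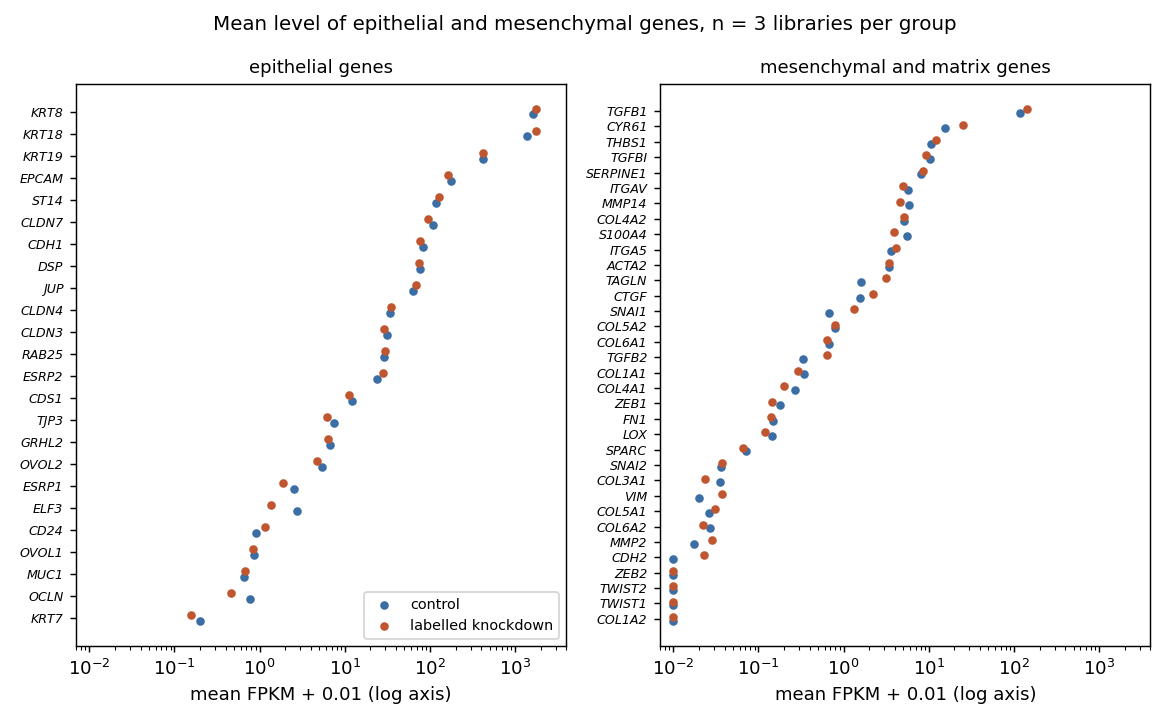
Mean FPKM + 0.01 (log axis) of each gene of the epithelial list and of the mesenchymal and matrix list, with 1 point per group (n = 3 libraries). KRT8 lies at 1613 and 1760 FPKM and VIM at 0.010 and 0.027 FPKM in control and labelled knockdown libraries.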

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

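The fit without the rows off the step grid and the voom fit were chosen after seeing the data. SRSF3 did not pass the threshold in any alternative run, with log2 changes from -0.12 to -0.02. The count of changed mRNA genes was 960 with no filter and 16 with a 2-fold minimum, and ran from 643 to 2742 with single libraries left out. The drop with no filter goes with more rows tested, and that with a 2-fold minimum with the minimum itself; the cause of the others was not tested. The lncRNA count of 0 became 12 at a mean of at least 1 FPKM, where fewer rows are tested, 1 with the replicate block and 57 with voom. Camera called 9 lists, and 0 with an estimated correlation. That correlation was 0.96 for mitochondrial mRNAs and 0.41 for ribosomal protein genes, far above the fixed 0.01. It was 0.015 for homologous recombination and 0.019 for cholesterol synthesis, near the fixed value. Among rows on the grid, homologous recombination had an estimated correlation of -0.0021, below the fixed value. Its camera adjusted p still went from 0.00127 to 0.107. Correlation between members therefore does not account for that loss, and other causes were not tested. A call lost with an estimated correlation is thus not by itself a sign of correlated members. Fry called 12, among them the lists of gemcitabine metabolism, p53 targets, mesenchymal, interferon-stimulated and NF-kB genes, which camera did not. The ANRIL difference, off the grid and untested, was -1.40 on log2(FPKM + 0.1) and -0.22 with a pseudocount of 1, which shrinks low values. Of 98 named genes past the threshold besides SRSF3, 63 kept their call in every alternative run for them and 35 lost it in at least 1; of their 1428 settings 1272 kept the call, 156 lost it and 0 changed sign. Among named genes not past it, 501 settings kept that, 50 passed the threshold and 2 changed sign or came to 0. With no filter TMEM14C, SRSF2, SRSF5, HNRNPH1, PTBP3, RBM15B, XRCC6, NME1, DCTPP1, CTPS1, XIAP, CLDN7, HIST1H2BK, MT-ND2, GEN1 and SLX4 lost their calls, with adjusted p from 0.0526 (CLDN7) to 0.265 (MT-ND2). ABCC1, not past it, had a log2 change of 0.07, and from -0.0015 (without control library 2) to 0.1675 with single libraries left out; the cause was not tested. AL161431.1 had the highest value of its table in each library, so quantile normalization sets its log2 change to 0, which says nothing about the 0.53 reported. Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at 0.08, 0.04 and 0.28 in the mRNA table, and those of differently numbered libraries at -0.21 to 0.15. In the lncRNA table they correlated at -0.01, -0.06 and 0.01, against -0.04 to 0.04. With quantile normalization 27 mitotic, 17 cholesterol synthesis and 17 unfolded protein genes fell, against 20, 15 and 12. With the replicate block the mRNA count was 2323. Transcripts summed per gene and the authors' own calls were not run, since the tables hold genes and no calls. At 1 FPKM a row of either table rests on 24.6 to 27.4 fragments per kilobase.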

Other observations

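The tests of explanations here were chosen after the result was seen, while the list tests were not. Stress and inflammatory genes not tied to the study's question also moved singly. Of 27 p53 target genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.235), among them the secreted stress factor GDF15, from 567.8 ± 29.0 to 845.9 ± 21.04 FPKM, AEN, PLK2 and PLK3. NF-kB cytokine genes had 4 of 15 higher (4 adjusted over the list alone, camera adjusted p = 0.107, and 0.0819 and 0.0373 after median scaling and quantile normalization), with NFKB2 from 24.1 ± 0.939 to 31.8 ± 2.43 FPKM and RELB and ICAM1 by 0.45 and 0.32 (log2). Interferon-stimulated genes had 5 higher and 2 lower of 30 (the same adjusted over the list alone, camera adjusted p = 0.414), with OASL at 25.6 ± 1.01 and 32.5 ± 1.27 FPKM. Apoptosis regulators had 3 higher and 4 lower of 25 (4 and 4 adjusted over the list alone, 1 and 4 with quantile normalization, camera adjusted p = 0.628, median 0.00 and mean -0.02 on the log2 scale). The inhibitor BCL2L1 rose by 0.24 (log2), a call lost without control library 2 (adjusted p = 0.0776), control library 3 (0.0836) or knockdown library 2 (0.0629), and the inhibitor XIAP fell by 0.35 (log2), a call lost without control library 2 (0.0548) or control library 3 (0.0880). Of 10 tested histone genes, a list fixed as a sign of RNA quality or handling, HIST1H2BK rose by 0.28 (log2; 1 adjusted over the list alone, camera adjusted p = 0.414), a call lost with quantile normalization (0.0716) and without control libraries 2 and 3 (0.108 and 0.0673) or knockdown libraries 1 and 2 (0.0531 and 0.0649).

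Epithelial genes were abundant in both groups, with KRT8 at 1613 ± 46.8 and 1760 ± 150 FPKM and CDH1 (E-cadherin) at 82.3 ± 1.29 and 75.5 ± 4.06 FPKM. Of 23 tested epithelial genes 3 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.165, and 0.164 and 0.0110 after median scaling and quantile normalization, with 6 lower and 0 higher in the latter). ELF3 fell from 2.76 ± 0.117 to 1.36 ± 0.104 FPKM, and CLDN7 by 0.19 (log2), a call lost without control libraries 1, 2 and 3 (0.0888, 0.155 and 0.1003). Of 16 tested mesenchymal and matrix genes, 6 rose, with CYR61 from 15.6 ± 0.871 to 25.1 ± 0.667 FPKM and TAGLN, and 2 fell, S100A4 and MMP14 (the same adjusted over the list alone, camera adjusted p = 0.388). Markers of other cells were mostly at the floor, with 12 of 14 leukocyte, 8 of 10 endothelial, 11 of 12 hepatocyte and 14 of 16 pancreatic genes below 0.5 FPKM, the exceptions including PDX1 at 9.78 ± 1.09 and 10.8 ± 1.06 FPKM and HNF4A at 7.65 ± 0.602 and 7.32 ± 0.426 FPKM. Across 10799 genes on the grid, which are not independent replicates, the fold change had a Spearman correlation of -0.20 with gene length and 0.28 with mean level. The median log2 change was 0.07 among the shortest genes and -0.04 among the longest. By mean level it was -0.02 among the lowest genes and 0.11 among the highest. The list tests were not adjusted for length or level, so these trends can be part of a list's result.

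PANC-1 is usually described as a vimentin-positive line, and here VIM was listed at no more than 0.0389 FPKM in any of the 6 libraries. Of 34 mesenchymal and matrix genes 18 had a mean below 0.5 FPKM, against 1 of 24 epithelial genes. Of 26 hnRNP genes 3 lay below 0.5 FPKM too, among them HNRNPL (0.0136 and 0.00936 FPKM) and HNRNPR, which most cells use. A value near 0 in this table therefore need not mean an unused gene. Loss of rows in the annotation or counting may account for the low mesenchymal values. It would not give the abundant epithelial genes, whose median level was 27.8 FPKM. Another cell line, or a changed state of the line after drug selection, may account for the low and the high values. No profile of the parent line was analysed here, so for the low mesenchymal values these explanations cannot be told apart.

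Among the 28 rows off the step grid, the off-grid values of the group that missed lay a median of 0.287 fragments from a whole number, against a tolerance of 0.003, which argues against rounding. In 21 rows 1 group alone lay on the grid (75% of 28, against 7.9% of 1000 shuffled rows, Fisher's exact p = 4.92e-17), which argues against fractional counting or isoform lengths, since these reach both groups; for the other 7 rows those cannot be told apart from other causes, because neither group fits. Whole FPKM numbers of up to 30, added to or taken from the values of the group that missed, placed 19 of the 21 rows on the grid (16 with every value shifted), against a median of 1 and at most 5 with 99 sets of fractional shifts, though a shift of 26 in 1 library of BRCA2, and shifts in PML that leave its controls at 1.83, 7.46 and 6.62 FPKM, may be chance placements. In those 19 rows the median size of the log2 change was 0.87 as deposited and 0.19 after the shifts, and in SIRT6 the shift was 9 in all 3 controls; a candidate explanation is therefore that whole numbers entered these values after FPKM were calculated; the files do not show how or why, and no biological explanation was tested.

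No fall of the SRSF3 row was detected in the libraries labelled knockdown. Too few fragments do not account for it, since the interval's lower bound is a change of -9.67%, nor does an exchange of libraries between the groups, since the lowest library stood at 93.4% of the highest, nor scaling, where the lowest log2 change was -0.12. A fall in protein or in 1 isoform, or one that had passed before RNA was taken, may still underlie the label: 0 other rows name an SRSF3 isoform or protein, so this cannot be told apart from a knockdown that did not take.

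The 6 libraries make only 10 splits into groups of 3, too few for a share under 0.05. The real split gave 1819 mRNA calls and the highest other split 1, so 1 of the 10 splits gave as many. In the lncRNA table all 10 splits, the real one included, gave 0 limma calls, so this comparison shows nothing; the real one had 284 rows at an unadjusted p under 0.05 and 57 voom calls, not counted in the other splits. For gene lists 2 of the 10 splits gave 9 called lists, the real one and that of control 1, control 3 and knockdown 2 against the rest. Mitosis passed in 8 of the other splits, with a smallest adjusted p = 4.62e-09 against 1.23e-13, and ribosomal protein genes reached 4.94e-09 in another split against 0.00334. Since part of any real difference stays in each other split, these are not comparisons without a change. That part does not account for a result stronger than in the real split. An adjusted p as small as the real one came from 5 of the 10 splits for ribosomal protein genes and 6 for mitochondrial mRNAs, the real split included. These 2 lists therefore also vary apart from the labels.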
